A study of Mus musculus with 24 samples.

How the data were processed

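The libraries came from the hippocampus of female, age-matched mice in 3 groups of 4 animals, with 1 input and 1 m6A IP library per animal. Per the labels' protocols, poly(A) RNA was split, 10% of 150 ng served as input and the rest was bound with a polyclonal anti-m6A antibody, eluted with free N6-methyladenosine, and both parts were made into libraries by the SMART-seq method, which copies RNA from the poly(A) tail. The protocol used here names no fragmentation of the RNA before the antibody step, so that IP values are read per transcript and not per site. Amplified cDNA has no molecular identifiers, so counts are not independent molecules and floors cover counting error only.

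The estimated counts per gene symbol were deposited by the authors, and the submitters' processing notes name bcl2fastq 2.17.1.14, Trimmomatic 0.32, STAR 2.7.6a, Salmon 1.4.0, SAMtools 1.10 and MACS2 2.1.2 with the builds GRCm38 and mm10, which are names of the same assembly. These estimated counts divide reads that fit several transcripts, 22.1% of the values were not whole, and they were rounded to whole numbers before testing. The authors also deposited TPM, transcript abundances scaled by transcript length to a fixed total per library. Per the file headers, peaks were called for each animal with MACS2 on read 1 of its IP library against its own input, with a genome size of 1e8, a q cutoff of 0.5, subpeak summits, no shifting model, an extension of 200 bases and an automatic duplicate limit. Each deposited peak carries its pileup signal at the summit, its −log10 p and −log10 q value and its fold enrichment over the local background, all as the authors' caller gave them, and these were used only to describe and filter peaks within a list. Per the file headers, 35 to 66% of tags were duplicates that were then limited, and the larger library of each pair was scaled down to the smaller.

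The count table held 55291 gene rows, of which 53292 matched a symbol in the reference table of GRCm38.p6 genes from RefSeq, used for gene positions and types. No row lacked a gene name and no column lacked a sample. The libraries held 3.98 to 48.6 M counts (M, megacounts). Animals are separate mice per the labels, so each animal was counted as a replicate, and nothing in the labels gives a batch. Numbers 1 to 4 did not pair animals across groups, whereas input and IP of the same number came from the same animal, which every one of the 12 pairs bore out by correlating best with each other.

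Expression was tested on the 12 input libraries and m6A enrichment on all 24, both with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, low-count filter by group with a minimum count of 10, Benjamini-Hochberg adjusted p below 0.05). The 12 input libraries shared a dispersion estimate, with 9 residual degrees of freedom, a prior of 5.47 and a median biological coefficient of variation of 0.225. The m6A fit had the animal as a block and the interaction of IP with group, with 9 residual degrees of freedom, a prior of 7.46 and a median of 0.170. It compares ratios of IP to input scaled over all libraries and cannot show a change of total m6A. Tests were 2-sided. Fold changes of genes were taken from these fits and means ± SD from CPM.

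Gene lists, 32 of them with at least 5 tested members, covered the cell types of the hippocampus and its surroundings, blood, glial states, m6A and H3K9 enzymes, neuronal and metabolic pathways. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry, which asks whether the genes of a list move one way or, in its mixed form, change in either direction, without comparing them with other genes. Tp53inp2 was the only list gene absent from the table. Genes were named by a rule fixed in advance. App, Thy1, Ehmt1, Ehmt2, Mettl3, Mettl14, Fto, Alkbh5, Gfap, Cst7, Trem2 and the sex genes Xist, Ddx3y, Eif2s3y, Kdm5d and Uty were among those always considered. For each comparison the 8 largest changes each way were added among genes with adjusted p below 0.05, a mean log2 CPM of at least 1 and no overlap of the groups, or, where fewer than 5 passed, the smallest p values up to 5; for each described list up to 4 members with the smallest p, and 3 peaks per direction. Predicted genes and pseudogenes were passed over, and 2 genes that met the rule are not reported here. The samples, tests, lists, naming rule and alternatives were chosen before the data were examined, except the added alternatives, the label check and the tests of weighed patterns.

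Peak numbers were compared with an exact permutation test over 70 assignments. Peaks of all 12 lists were merged where they overlapped by at least 1 base, and a merged peak was counted for a group when found in at least 3 of its 4 animals and in none of the other group. Correlations with depth used 100000 permutations. Opposite changes between comparisons that share libraries were set beside simulated unchanged groups, and both these and overlaps of calls beside splits of the shared animals. For the input and IP parts of the m6A change, genes were also chosen and measured in different animals. For Gm10259 and other genes with 0 counts in a group, a floor of 3 counts over the group was used. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

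The edgeR steps were tested on simulated data with 200 changed genes. Among 17262 genes for expression of vehicle against wild-type, 25.4% of 1.5-fold, 64.2% of 2-fold and 95.5% of 4-fold changes were recovered with 5 unchanged genes among 128 calls, and for MS1262 against vehicle 23.9%, 64.2% and 95.5% with 5 among 127. Among 17937 genes for m6A enrichment the shares were 19.4%, 61.2% and 89.4% for vehicle against wild-type (6 unchanged of 119 calls) and 13.4%, 64.2% and 92.4% for MS1262 against vehicle (2 of 115). With no change simulated between MS1262 and wild-type, 0 genes were called.

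Alternatives were DESeq2 1.42.0, other scalings, no filter and stricter filters, limma on log2(TPM + 1) and log2(TPM + 0.1), fits on the libraries of both groups only, the replicate number as a block, IP libraries alone, limma on the IP minus input difference per animal, stricter peak thresholds and overlaps, and each animal left out in turn. The removal of a length trend from the m6A values and the omission of vehicle animals 3 and 4 together were added after the data had been seen.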

Results

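Hippocampal poly(A) RNA of 12 mice, all female by their labels, was profiled by m6A RNA immunoprecipitation and sequencing (MeRIP-seq). In this assay an antibody against N6-methyladenosine (m6A), the most common internal modification of messenger RNA, enriches the transcripts that carry it. The animals formed 3 groups of 4: wild-type mice with no treatment, 5xFAD mice given vehicle and 5xFAD mice given MS1262. 5xFAD mice carry human transgenes with familial Alzheimer's disease mutations under the Thy1 promoter, and develop amyloid plaques with gliosis. MS1262 is, by the series title, a brain-penetrant inhibitor of G9a, the histone H3K9 methyltransferase that Ehmt2 encodes. Each animal gave 1 input library, which measures expression, and 1 immunoprecipitated (IP) library, 24 libraries in all. Expression and m6A enrichment were compared between groups. Against untreated wild-type mice, genotype and dosing cannot be told apart.

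Total counts of the input libraries, in megacounts (M), were 38.0, 40.7, 23.3 and 43.2 M for wild-type animals 1 to 4. They were 41.4, 20.7, 25.5 and 40.8 M for vehicle animals and 41.8, 24.8, 34.5 and 38.9 M for MS1262 animals. The IP libraries held 17.2, 48.6, 10.7 and 21.3 M for wild-type, 43.8, 20.5, 22.7 and 3.98 M for vehicle, and 26.0, 29.8, 28.3 and 43.2 M for MS1262 animals. Group means for input were 36.3 ± 8.90, 32.1 ± 10.6 and 35.015 ± 7.43 M (wild-type, vehicle and MS1262, SD, n = 4). For IP they were 24.4 ± 16.7, 22.7 ± 16.3 and 31.8 ± 7.76 M. In a check of the labels by sex-linked genes, made after the data were seen, 2 of 24 libraries, both of 1 animal, did not match their group's labels.

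To see which transcripts the antibody enriched, IP was compared with input within each animal. Bcl2l1, which encodes the apoptosis inhibitor Bcl-xL, was enriched 6.80-fold (log2 2.76, SE 0.08, edgeR adjusted p = 5.67e-13), with the same sign in every animal. Others at the top were clustered protocadherins, neuronal adhesion genes: Pcdhgc3 had log2 4.42 (SE 0.23), Pcdhga4 3.97, Pcdhgc5 3.66, Pcdhga6 3.64, Pcdhga11 3.55, Pcdhga7 3.34 and Pcdhga3 3.25. Protocadherin transcripts share exons, so the split of reads among them is uncertain. Depleted in the IP were mt-Nd3, a mitochondrial complex I subunit gene (log2 −2.45, SE 0.15), Tcte1 (−2.33) and the mitochondrial ribosomal RNA mt-Rnr1 (−2.15). The ribosomal protein genes Rps14 (−1.88) and Rps28 (−1.77), the chaperone gene Canx (−1.76), Siva1 (−1.90) and Pcdha4 (−1.88) were depleted as well. In total 10227 of 18300 tested genes passed, 5158 higher in the IP and 5069 lower, and 1843 changed at least 2-fold.

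Most genes named in advance differed between IP and input. Gfap (log2 1.404), Fto (0.98), Ehmt2 (0.73), Mettl14 (0.35), Mettl3 (0.30) and Ehmt1 (0.28) were higher in the IP, the last 3 not in every animal. Alkbh5 (−0.57) and App (−0.42) were lower in every animal. Trem2 passed at 0.21, an average of groups of opposite sign, with an IP minus input difference of −0.65 ± 0.30 log2 CPM in wild-type, 0.70 ± 0.22 in vehicle and 0.61 ± 0.27 in MS1262 animals (SD, n = 4). Cst7 passed at −0.53, which came from wild-type animals (−1.37 ± 1.49, with at most 7 IP counts), while vehicle and MS1262 animals lay at 0.01 ± 0.24 and 0.24 ± 0.23. Thy1 (0.07, adjusted p = 0.426) and Xist (−0.20, adjusted p = 0.112) did not pass. The Cst7 call ended without wild-type animal 2 or 4 (adjusted p up to 0.0985; 0.00240 at the lowest over single omissions). The Trem2 call ended without wild-type 3 or 4, vehicle 4 or MS1262 3 or 4 (up to 0.0932; 0.00929 at the lowest). Xist passed without vehicle 1 (adjusted p = 0.0137, highest 0.321).

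By gene list, all 15 mitochondrially encoded genes were lower in the IP (median log2 −1.30, camera adjusted p = 2.41e-07, 0.702 at estimated correlation). Of 80 ribosomal protein genes 63 were lower and 10 higher (median −0.45, adjusted p = 1.12e-08, 0.816 at estimated correlation). Of 29 oxidative phosphorylation genes 21 were lower and 4 higher (median −0.37, adjusted p = 0.00134, 0.816 at estimated correlation). Lysosomal genes were enriched in the IP (12 of 22 higher, adjusted p = 0.00684, 0.551 at estimated correlation). So were oligodendrocyte precursor markers (6 of 10 higher, adjusted p = 0.0286, 0.504 at estimated correlation). Homeostatic microglia markers were enriched too (10 of 16 higher, adjusted p = 0.0432, 0.551 at estimated correlation).

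Microglial genes were higher in the hippocampus of 5xFAD mice given vehicle than in wild-type mice. Cst7 encodes the protease inhibitor cystatin F and marks microglia at plaques (GRCm38 chromosome 2, 150570415 to 150578944). It rose 76.3-fold, from 0.376 ± 0.130 to 30.3 ± 21.7 CPM (SD, n = 4 animals per group, log2 6.25, SE 0.61, edgeR adjusted p = 0.000124). The lectin receptor gene Clec7a rose 13.6-fold (log2 3.77, SE 0.53, adjusted p = 0.00259) and the chemokine gene Ccl6 10.8-fold (log2 3.43, SE 0.46, adjusted p = 0.00182). The protease gene Ctse rose 34.5-fold (log2 5.11, SE 0.75, adjusted p = 0.00351). The antigen presentation genes Cd74 (7.89-fold) and H2-Aa (5.73-fold, adjusted p = 0.0237) and the leukocyte surface gene Cd52 (6.31-fold) also rose. The centromere chaperone gene Hjurp rose from 2.20 ± 0.825 to 11.9 ± 0.857 CPM. Thy1, a neuronal surface gene whose promoter drives the transgenes, rose 4.90-fold (96.1 ± 8.74 to 471 ± 202 CPM, log2 2.29, SE 0.24, adjusted p = 0.000239). Gfap, the intermediate filament gene of astrocytes, rose 2.88-fold (77.4 ± 35.1 to 223 ± 116 CPM, adjusted p = 0.0449).

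**Figure D1:**
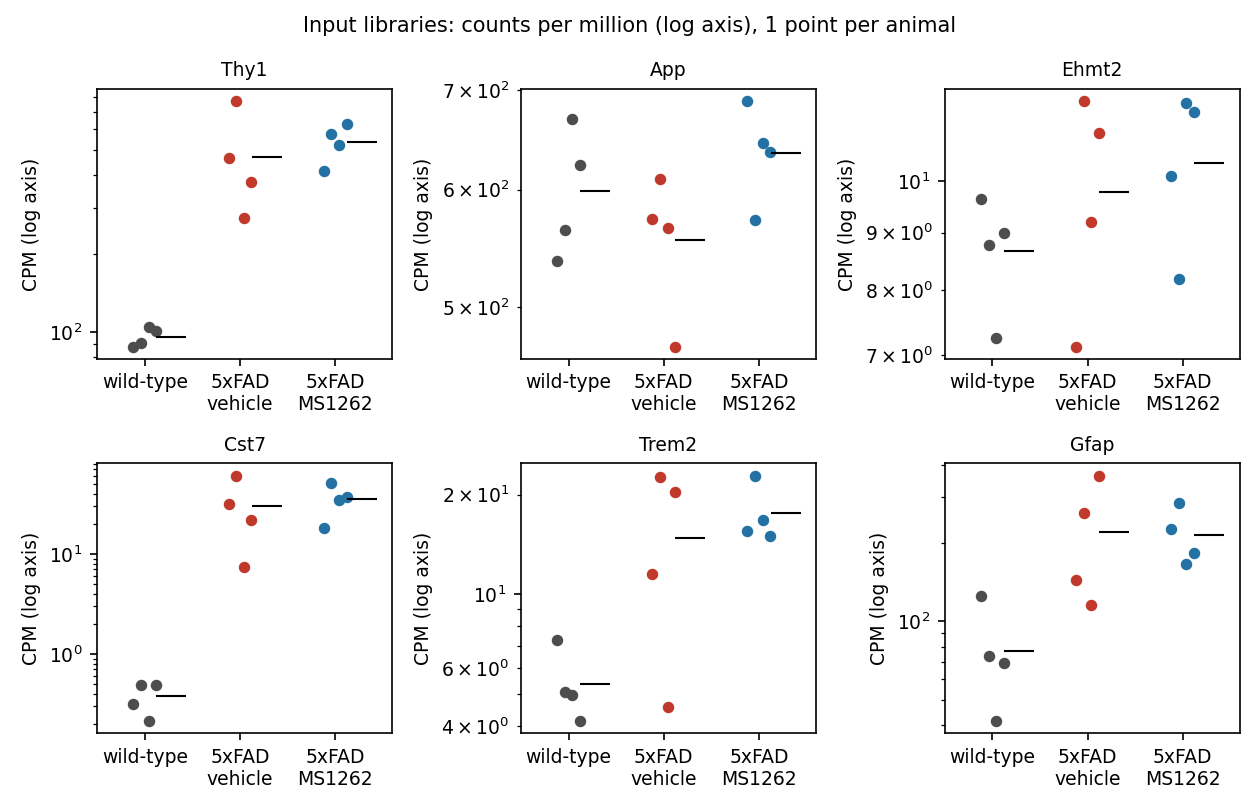
CPM in the 12 input libraries for 6 named genes on a log axis, 1 point per animal, with a line at each group's mean. For Cst7 the 4 vehicle and 4 MS1262 animals lie above the wild-type animals, whose mean was 0.376 CPM.

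Other genes were lower in 5xFAD vehicle than in wild-type animals. Tmem242, a mitochondrial assembly factor gene on chromosome 17, fell from 103 ± 34.2 to 11.2 ± 0.699 CPM (log2 −3.21, SE 0.19, edgeR adjusted p = 6.71e-07). The RNA-binding gene Lsm12 on chromosome 11 fell from 50.1 ± 8.05 to 5.72 ± 1.02 CPM (log2 −3.13, SE 0.19). The microtubule regulator gene Clasp2 fell from 154 ± 10.3 to 65.7 ± 3.41 CPM (log2 −1.22, SE 0.09, adjusted p = 3.57e-06). The noncoding Gt(ROSA)26Sor (−2.68), the microRNA host transcript Mir124-2hg (−1.77), the dynein light chain gene Dynlt1b (−1.14), Lrrc49 (−1.1003) and Frat1 (−0.96) fell too. Dynlt1b has near-identical copies, so its share of reads is uncertain. App (log2 −0.10, adjusted p = 0.726), Ehmt1 (0.18), Ehmt2 (0.18) and the microglial receptor gene Trem2 (1.46, adjusted p = 0.0685) did not pass. Neither did the m6A methyltransferase genes Mettl3 (0.13) and Mettl14 (−0.27), the demethylase genes Fto (0.13) and Alkbh5 (−0.32) or Xist (−0.02).

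In total 278 of 17693 genes differed between vehicle and wild-type animals, 187 higher and 91 lower, 147 of them at least 2-fold (edgeR adjusted p below 0.05). DESeq2 called 611. The split turned on the TPM scale, where limma called 60 higher and 195 lower with log2(TPM + 1) and 81 higher and 200 lower with log2(TPM + 0.1). On that last scale the median of all genes lay at −0.14, so the changes of genes and lists are relative to the TMM scale. Leaving out wild-type animal 1, 3 or 4 gave 142, 141 or 108 genes, and leaving out vehicle animal 1 or 2 gave 162 or 116. The H2-Aa call ended without any of the wild-type animals or vehicle 1 or 2 (adjusted p up to 0.0746; 0.000844 to 0.0746 over all alternatives). The Gfap call ended without wild-type 2, 3 or 4 or vehicle 1, 2 or 4 (up to 0.130; 0.00238 to 0.130). Trem2 passed without vehicle 3 (adjusted p = 0.00155, highest over single omissions 0.198). Ctse missed the threshold with log2(TPM + 1) in limma (adjusted p = 0.0543).

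Glial lists were higher in 5xFAD vehicle than in wild-type mice. Of 30 genes of the disease-associated microglia signature 20 rose and none fell (25 adjusted over the list alone, median log2 1.46, camera adjusted p = 1.59e-28). Among them were the integrin gene Itgax (55.5-fold, log2 5.80, SE 0.69), the chemokine gene Ccl3 (39.6-fold) and the lysosomal protease gene Ctsd (2.69-fold). Homeostatic microglia markers rose as well, 5 of 16 over all genes and 13 adjusted over the list alone (median 0.79, adjusted p = 9.56e-13, 0.0927 at estimated correlation). Olfml3 was up 2.71-fold, Tmem119 4.25-fold, the receptor gene Fcrls 5.19-fold and the fractalkine receptor gene Cx3cr1 2.01-fold. Of 20 complement and antigen presentation genes 8 rose (16 adjusted over the list alone, median 1.25, adjusted p = 1.99e-15), with C3ar1 at 5.35-fold, C4b at 3.65-fold and C1qc at 2.86-fold. Of 19 reactive astrocyte genes 4 rose (11 adjusted over the list alone, median 0.81, adjusted p = 2.26e-08), including the oncostatin receptor gene Osmr at 2.95-fold and the chemokine gene Cxcl10 at 5.29-fold. The complement count fell to 5, 4, 3 and 2 without wild-type 1 to 4 and to 5 without vehicle 1, 2 or 4. The reactive astrocyte count fell to 2, 2, 1 and 1 without wild-type 1 to 4 and to 2, 1 and 2 without vehicle 1, 2 and 4, with 6 adjusted over the list alone without vehicle 2. Without vehicle 3 the homeostatic count rose to 9 and the complement count to 12.

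Lysosomal genes rose with the glial ones, 8 of 22 over all genes and 17 adjusted over the list alone (median 0.56, adjusted p = 3.60e-15). The cholesterol carrier gene Npc2 was up 1.59-fold (SE of log2 0.08), the cathepsin genes Ctsh 2.46-fold and Ctsa 1.73-fold, and the progranulin gene Grn 1.95-fold. General astrocyte markers lay at a median of 0.23 (0 of 15 called, 1 adjusted over the list alone, adjusted p = 0.000422, 0.0934 at estimated correlation), with the water channel gene Aqp4 at log2 0.53. Interferon response genes lay at 0.48 (1 of 19 called, 5 adjusted over the list alone, adjusted p = 0.000146, 0.270 at estimated correlation). Of these, Ifitm3 rose 1.75-fold. The lysosomal count fell to 5, 5, 4 and 3 without wild-type 1 to 4 and to 5 and 4 without vehicle 1 and 2. No interferon gene was called without any of the wild-type animals or vehicle 1 or 2, and 1 to 3 passed adjusted over the list alone in every omission but that of vehicle 3. For astrocyte markers 0 to 3 passed adjusted over the list alone, and 1 was called over all genes without vehicle 4.

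**Figure D2:**
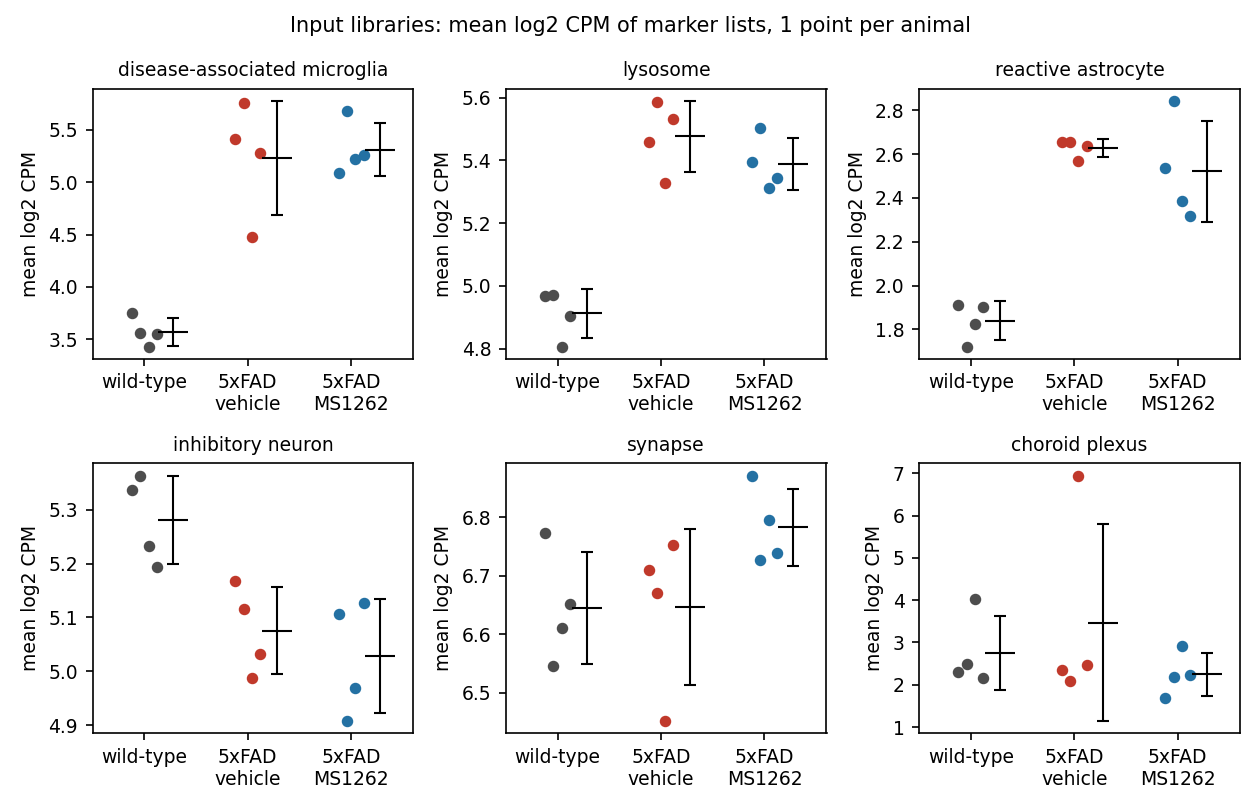
Mean log2 CPM of 6 gene lists in the 12 input libraries, 1 point per animal, with the mean and SD of each group. Vehicle animal 3 lies at 6.94 for choroid plexus markers, and the next vehicle animal at 2.48.

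Metabolic lists also changed between vehicle and wild-type mice. The 15 mitochondrially encoded genes were higher, 5 over all genes and 12 adjusted over the list alone (median log2 0.38, camera adjusted p = 4.35e-11, 0.201 at estimated correlation). The count over all genes fell to 2, 2 and 1 without wild-type 1, 2 and 4 and to 2 without vehicle 1, 2 or 4, whose own omission left a median of 0.29. The cytochrome oxidase gene mt-Co3 led with 1.51-fold (SE of log2 0.10). Mitochondrial genes took 14.03 ± 1.87% of input counts in vehicle and 10.7 ± 0.856% in wild-type animals (SD, n = 4). Cholesterol synthesis genes were higher (0 of 20 called, 9 adjusted over the list alone, median 0.32, adjusted p = 5.58e-06, 0.158 at estimated correlation). Proliferation genes rose as a list (median 0.53, adjusted p = 0.000950), with 1 of 16 called over all genes and adjusted over the list alone, the mitotic kinase gene Cdk1 at 2.78-fold. Amyloid processing genes rose as well (2 of 21 called, 4 adjusted over the list alone, median 0.09, adjusted p = 0.0211, 0.0934 at estimated correlation). The 2 called members were Thy1, the transgenes' promoter gene, and the apolipoprotein gene Clu at 1.44-fold, neither of which cleaves APP. Omissions ended the Cdk1 call (wild-type 1 or 4, vehicle 1 or 2), left 1 amyloid gene called (wild-type 3 or 4, vehicle 2) and left 0, 1 and 0 cholesterol genes adjusted over the list alone (wild-type 4, vehicle 1 and 2). Without vehicle 3, 3 cholesterol genes were called over all genes.

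Inhibitory neuron genes fell as a list (median −0.15, adjusted p = 0.0310, 0.158 at estimated correlation). The somatostatin gene Sst fell over all genes (log2 −0.81, SE 0.17, edgeR adjusted p = 0.0306), and 1 of 16 members passed adjusted over the list alone. Immediate early genes, which neuronal activity induces, lay at a median of −0.52 (0 of 21 over all genes and adjusted over the list alone, adjusted p = 0.00895, 0.572 at estimated correlation). The ribosomal protein list passed upward (adjusted p = 0.0163, 0.745 at estimated correlation), with a median of 0.08 and a mean of −0.07, so that median and mean differed in sign. Of its 80 members Rpl29 rose 1.71-fold and the pseudogenes Rps3a2 and Rps3a3 fell, both over all genes and adjusted over the list alone. The Sst call ended without wild-type 1 or 2 or vehicle 1 or 2, and that of Rpl29 without wild-type 1 or 4 or vehicle 1 or 2. Without vehicle 4, 1 immediate early gene was lower over all genes and 5 adjusted over the list alone.

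Markers of blood and of tissue next to the hippocampus also moved in this comparison. Meninges and fibroblast markers (median 0.65, 0 of 14 over all genes and adjusted over the list alone) passed at adjusted p = 0.0119, but had 0.572 at estimated correlation. Red blood cell genes (median 0.65, 0 of 5 over all genes and adjusted over the list alone) passed at adjusted p = 0.0211, but had 0.568 at estimated correlation. Choroid plexus markers lay at a median of 2.08 and did not pass (adjusted p = 0.143). In the input library of vehicle animal 3 the choroid plexus transcript Ttr reached 12.78 log2 CPM, against 4.92 to 9.55 in the other input libraries. In all, 16 of 32 lists passed, 14 higher and 2 lower. With an estimated correlation 5 held: disease-associated microglia, complement and antigen presentation, reactive astrocyte, lysosome and proliferation. The lysosome list held so in all 8 single omissions (adjusted p up to 0.0165), and the others only in that of vehicle 3 (up to 0.126, 0.126, 0.0911 and 0.148 in the order disease-associated microglia, complement, reactive astrocyte and proliferation). fry called 11. Adjusted over the list alone, 8 meninges genes passed without vehicle 2, 4 red blood cell genes without wild-type 2, and 8, 11, 11 and 11 choroid plexus genes without wild-type 3 and vehicle 1, 2 and 4.

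Calls of the weaker lists in vehicle against wild-type mice rested on single animals. The inhibitory neuron call ended without wild-type 1 or 2 or vehicle 3 or 4 (adjusted p up to 0.157; 0.00881 to 0.496 over all alternatives). The immediate early gene call ended without wild-type 3 or vehicle 2 or 3 (up to 0.308; 0.000162 to 0.572) and the meninges call without wild-type 2 or vehicle 3 or 4 (up to 0.146; 6.12e-07 to 0.749). The red blood cell call ended without wild-type 1 or 4 or vehicle 1 or 4 (up to 0.116; 0.000535 to 0.568). The amyloid processing call ended without wild-type 2 or vehicle 3 (up to 0.101; 0.00251 to 0.102) and the ribosomal protein call without wild-type 4 or vehicle 1 or 4 (up to 0.804; 0.000706 to 0.804). Choroid plexus markers passed upward without wild-type 3 or vehicle 1, 2 or 4 (0.00875 at the lowest, 0.395 at the highest over single omissions). Without vehicle 3 they were lower than in wild-type animals (median −0.64, adjusted p = 0.0337, 0.670 at estimated correlation).

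MS1262 was compared with vehicle in 5xFAD mice to ask what the inhibitor changes, and no gene passed the edgeR test. Among glial genes, Cst7 was at 35.3 ± 14.1 CPM with MS1262 and 30.3 ± 21.7 CPM with vehicle (SD, n = 4, log2 0.22, SE 0.44, edgeR adjusted p = 0.948). Trem2 was at 17.4 ± 3.79 and 14.8 ± 8.18 CPM (0.23, SE 0.35) and Gfap at 214 ± 52.8 and 223 ± 116 CPM (−0.06, SE 0.34). The G9a gene Ehmt2 was at 10.3 ± 1.70 and 9.83 ± 1.94 CPM (log2 0.07, SE 0.18, adjusted p = 0.961). Ehmt1, which encodes its partner GLP, was at 19.2 ± 3.395 and 15.8 ± 1.51 CPM (0.29, SE 0.15, adjusted p = 0.863). App (0.17), Thy1 (0.18), Mettl3 (−0.09), Mettl14 (0.12), Fto (−0.13), Alkbh5 (0.27) and Xist (0.17) did not pass.

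The genes with the smallest p values in MS1262 against vehicle, none of which passed, went both ways. Higher were Klhl42 (log2 0.60), Tmem63b (0.94), Pcdha6 (1.405), Tma16 (0.48) and the neutrophil chemokine gene Cxcl5 (1.32). Lower were the phosphatase gene Acp1 (−0.48), Ttc23 (−1.04), the coagulation factor gene F13a1 (−1.45), Tnfaip8 (−0.70) and Mr1 (−0.56). In total 0 of 17693 genes had an edgeR adjusted p below 0.05, the smallest was 0.848, and 1003 had an unadjusted p below 0.05. DESeq2 called 11, 4 higher and 7 lower, and both limma fits on log2 TPM called 0. Without vehicle 2 there were 2 genes, among them F13a1 (adjusted p = 0.00751, highest over single omissions 0.990). Without vehicle 3 there was 1, and without vehicle 3 and 4 together there were 2.

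Synaptic and excitatory neuron lists were slightly higher with MS1262 than with vehicle, and no member of any list was called over all genes. Synaptic genes had a median log2 of 0.15 (26 of 30 positive, camera adjusted p = 0.000337, 0.405 at estimated correlation). Examples are the presynaptic genes Nrxn3 (0.23, SE 0.11) and Pclo (0.23, SE 0.12) and the NMDA receptor subunit gene Grin2a (0.33, SE 0.17). Excitatory neuron genes had a median of 0.16 (11 of 14 positive, adjusted p = 0.00315, 0.372 at estimated correlation), with the transcription factor gene Neurod2 at 0.52 (SE 0.18). The excitatory neuron call rested on vehicle 3 (list mean 6.31 log2 CPM, against 6.63 to 6.84 in the other vehicle animals) and ended without it (adjusted p = 0.0796; 0.000869 to 0.372 over all alternatives). Inhibitory neuron genes did not pass and had a negative median (−0.03, 7 of 16 positive, adjusted p = 0.641). In the synaptic and excitatory lists 0 members passed adjusted over the list alone.

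Ribosomal protein genes (median −0.13, adjusted p = 1.88e-07), oxidative phosphorylation genes (−0.13, adjusted p = 0.000327) and mitochondrially encoded genes (−0.18, adjusted p = 8.95e-05) were lower with MS1262. Each gave adjusted p = 0.480 at estimated correlation and 0 members adjusted over the list alone. Examples are Rpl3 (log2 −0.33, SE 0.10), the complex II gene Sdha (−0.22, SE 0.09) and mt-Nd4l (−0.29, SE 0.10). Endothelial and mural markers (median −0.49, Vtn at −0.91, 0 of 18 adjusted over the list alone) were lower at adjusted p = 2.49e-05, but had 0.372 at estimated correlation. Red blood cell genes (median −1.18, the globin gene Hbb-bs at −1.28, 3 of 5 adjusted over the list alone) were lower at adjusted p = 7.60e-05, but had 0.372 at estimated correlation. Without vehicle 1 or 4 or MS1262 1, 2 or 3 no red blood cell gene passed over the list alone, and without MS1262 4 all 5 did.

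Choroid plexus markers had a median of −2.77 in MS1262 against vehicle (14 of 14 lower adjusted over the list alone, adjusted p = 0.000550, 0.530 at estimated correlation). The potassium channel gene Kcnj13 (log2 −3.52, SE 1.06) and the claudin gene Cldn2 (−3.05, SE 0.95) led. Meninges and fibroblast markers were lower (median −0.85, 5 of 14 adjusted over the list alone, Igf2 at −1.79, adjusted p = 3.17e-05, 0.415 at estimated correlation). Thalamus and striatum markers were lower as well (−0.69, 0 of 15 adjusted over the list alone, Tcf7l2 at −1.36, adjusted p = 0.0242, 0.491 at estimated correlation). The choroid plexus list had a mean of 6.94 log2 CPM in vehicle animal 3, and the other input libraries lay between 1.68 and 4.04. For meninges markers vehicle 2 stood apart on the low side (1.75, against 3.11 to 3.305 in the other vehicle animals). Adjusted over the list alone, 0 choroid plexus genes passed without vehicle 3 or MS1262 1 or 2. The meninges count was 10 without vehicle 2 and 0 in the other omissions.

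Without vehicle animal 3 the choroid plexus median in MS1262 against vehicle was −0.11 (adjusted p = 0.966; 2.13e-06 to 0.966 over all alternatives) and the thalamus and excitatory neuron calls ended. Microglial lists then passed on the lower side. Disease-associated microglia genes had a median of −0.21 (25 of 30 negative, adjusted p = 0.00428, 0.448 at estimated correlation; 0.000136 to 0.987 over all alternatives). Homeostatic microglia markers had −0.20 (15 of 16 negative, adjusted p = 0.00326, 0.319 at estimated correlation). Complement and antigen presentation genes had −0.25 (17 of 20 negative, adjusted p = 0.0199, 0.342 at estimated correlation; 0.0199 to 0.988 over all alternatives). Astrocyte markers (−0.12, adjusted p = 0.0208, 0.319 at estimated correlation) and lysosomal genes (−0.15, adjusted p = 0.0122, 0.319 at estimated correlation) passed too. So did interferon response genes (−0.26, adjusted p = 0.00428, 0.411 at estimated correlation), and 0 lists passed fry at this setting or with all animals.

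With all 4 vehicle animals these glial lists did not pass. Disease-associated microglia genes had a median of 0.01 and a mean of −0.02, which differ in sign, with 15 of 30 positive (adjusted p = 0.833), homeostatic microglia −0.07 (0.966), reactive astrocyte genes −0.16 (0.501) and astrocyte markers −0.10 (0.128). Interferon response genes had −0.20 (0.144) and lysosomal genes −0.13 (0.0973). Complement and antigen presentation genes had a negative median (−0.05) and mean (−0.08) while the test pointed upward (adjusted p = 0.966). H3K9 methylation genes had a median of 0.09 (16 of 22 positive, adjusted p = 0.0973) and m6A writers 0.11 (9 of 12 positive, adjusted p = 0.0973). Of 32 lists 10 passed, 2 higher and 8 lower, with 0 passing at estimated correlation. The thalamus call ended also without MS1262 2 or 4 (adjusted p up to 0.574; 0.00141 to 0.574 over all alternatives). The oxidative phosphorylation call ended without MS1262 1 (0.0559; 3.66e-05 to 0.480) and the mitochondrially encoded call without vehicle 4 (0.0728; 2.28e-06 to 0.480). Disease-associated microglia genes passed without vehicle 2 as well (0.0485), interferon genes without MS1262 4 (0.00495), lysosomal genes without MS1262 2 (0.0267) and H3K9 genes without MS1262 2 (0.0358). The highest adjusted p of these 4 lists over single omissions were 0.788, 0.884, 0.443 and 0.164.

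5xFAD mice given MS1262 had microglial genes at the top of the comparison with wild-type mice. Cst7 was 89.0-fold higher (35.3 ± 14.1 against 0.376 ± 0.130 CPM, SD, n = 4, log2 6.48, SE 0.61, edgeR adjusted p = 8.91e-05). Ctse was 43.2-fold higher, Clec7a 12.3-fold, Ccl6 11.0-fold, Cd74 7.44-fold, the survival gene Bcl2a1b 6.93-fold, Cd52 6.50-fold and Hjurp 6.25-fold. Bcl2a1b has close paralogs and its share of reads is uncertain. Thy1 rose 5.55-fold (log2 2.47, SE 0.24, adjusted p = 0.000125) and Trem2 3.23-fold (log2 1.69, SE 0.37, adjusted p = 0.0355), while Gfap at 2.76-fold did not pass (adjusted p = 0.0582). Lower genes were Tmem242 (log2 −3.36, SE 0.19, adjusted p = 5.51e-07), Lsm12 (−3.05), Gt(ROSA)26Sor (−2.72), Mir124-2hg (−1.86), Dynlt1b (−1.45) and Clasp2 (−1.23). The protocadherin gene Pcdhb6 (−1.35, adjusted p = 0.0230) and the sodium pump regulator gene Fxyd2 (−1.15, adjusted p = 0.0329) were lower too. App (0.07), Ehmt1 (0.47, adjusted p = 0.155), Ehmt2 (0.25, adjusted p = 0.560), Mettl3 (0.04), Mettl14 (−0.16), Fto (−0.00), Alkbh5 (−0.05) and Xist did not pass.

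In total 230 genes differed between MS1262 and wild-type mice, 161 higher and 69 lower, 135 of them at least 2-fold (edgeR). DESeq2 called 633. On the TPM scale limma called 60 higher and 64 lower with log2(TPM + 1) and 79 higher and 66 lower with log2(TPM + 0.1). Leaving out wild-type 2, 3 or 4 gave 132, 124 or 137 genes, and leaving out MS1262 2, 3 or 4 gave 115, 105 or 136. The Pcdhb6 and Fxyd2 calls ended in 7 of 8 single omissions, all but that of wild-type 2 (adjusted p up to 0.0762 and 0.102; 0.00471 and 0.0246 at the lowest). The Trem2 call ended in 7 of 8, all but that of wild-type 1 (0.0484 to 0.116). Gfap passed without wild-type 1 (adjusted p = 0.0275, highest 0.164).

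The called genes of both 5xFAD groups overlapped. Of 187 genes higher with vehicle and 161 higher with MS1262, 114 were shared, against 1.70 for independent lists, but both comparisons share the wild-type libraries. When different wild-type animals served as controls for each group, 6 splits gave 12 to 24 shared genes (mean 17.3), with 0.101 for independent lists. Of 91 and 69 lower genes 40 were shared, against 0.355 for independent lists and 12 to 14 in the splits (mean 13.2).

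Microglial and astrocytic lists were higher in MS1262 than in wild-type mice. Of 30 disease-associated microglia genes 19 rose (25 adjusted over the list alone, median log2 1.44, camera adjusted p = 1.11e-27, 0.0516 at estimated correlation). Itgax was up 74.0-fold, Ccl3 40.2-fold and the lysosomal glycoprotein gene Cd68 4.77-fold. Homeostatic microglia markers were higher (5 of 16, 12 adjusted over the list alone, median 0.75, Olfml3 at log2 1.36, adjusted p = 6.77e-12, 0.0917 at estimated correlation). Complement and antigen presentation genes were higher (6 of 20, 16 adjusted over the list alone, median 1.102, adjusted p = 2.16e-14, 0.0564 at estimated correlation), with C3ar1 at 5.87-fold and C4b at 4.12-fold. Of 19 reactive astrocyte genes 4 rose (9 adjusted over the list alone, median 0.60, adjusted p = 1.45e-05, 0.0516 at estimated correlation). Osmr was up 3.68-fold and the intermediate filament gene Vim 1.93-fold. Of 22 lysosomal genes 7 rose (11 adjusted over the list alone, median 0.43, Grn at 2.06-fold, adjusted p = 1.36e-10, 0.0157 at estimated correlation). The lysosomal count fell to 3 without wild-type 3 and to 4 without wild-type 1 or 4 or any MS1262 animal. The reactive astrocyte count fell to 2 without wild-type 3 or MS1262 1, 2 or 3, and the homeostatic count to 3 without wild-type 2.

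Cholesterol synthesis, mitochondrially encoded, amyloid processing and proliferation lists were higher in MS1262 than in wild-type mice too. Cholesterol synthesis genes had a median of 0.31 (0 of 20, 11 adjusted over the list alone, Fdps at log2 0.53, adjusted p = 4.61e-06, 0.155 at estimated correlation). Mitochondrially encoded genes had 0.21 (0 of 15 over all genes and adjusted over the list alone, adjusted p = 0.000152, 0.517 at estimated correlation). Amyloid processing genes had 0.09 (2 of 21, 6 adjusted over the list alone, adjusted p = 0.00177, 0.0516 at estimated correlation), with Thy1 and the beta-secretase gene Bace1 (1.27-fold) called. Proliferation genes had 0.35 (0 of 16, 2 adjusted over the list alone, adjusted p = 0.00710, 0.0688 at estimated correlation). In each single omission 1 amyloid gene was called over all genes. Adjusted over the list alone, 5, 5 and 6 cholesterol genes passed without wild-type 4, MS1262 2 and MS1262 4, 9 mitochondrial genes without wild-type 3, 3 amyloid genes without wild-type 3, and 0 proliferation genes without wild-type 1, 2 or 4 or MS1262 2, 3 or 4.

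Further lists went both ways in MS1262 against wild-type mice. Inhibitory neuron genes were lower (median −0.15, adjusted p = 0.0252, 0.155 at estimated correlation). The interneuron peptide genes Sst (log2 −1.11, SE 0.17, edgeR adjusted p = 0.00480) and Npy (−0.73, SE 0.14, adjusted p = 0.0201) were lower over all genes, and 2 of 16 members adjusted over the list alone. Synaptic genes were higher (1 of 30, the presynaptic scaffold gene Bsn at 1.63-fold, 4 adjusted over the list alone, median 0.07, adjusted p = 0.0366, 0.517 at estimated correlation). So were interferon response genes (1 of 19, Trim30a at log2 1.52, 4 adjusted over the list alone, median 0.33, adjusted p = 0.0225, 0.517 at estimated correlation). Astrocyte markers were higher (0 of 15, 2 adjusted over the list alone, median 0.11, adjusted p = 0.0492, 0.413 at estimated correlation). Endothelial and mural markers were lower (median −0.25, 0 of 18 over all genes and adjusted over the list alone, adjusted p = 0.0248, 0.517 at estimated correlation). Oxidative phosphorylation genes were lower (median −0.13, 1 of 29, Sdhb at −0.42, 2 adjusted over the list alone, adjusted p = 0.00391, 0.517 at estimated correlation). The Sdhb call ended in every single omission, that of Bsn without wild-type 2, 3 or 4 or MS1262 1, 3 or 4, and no interferon gene was called except without MS1262 1 (2 genes). Only 1 inhibitory gene was called without wild-type 1 or MS1262 2, 3 or 4.

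Of 32 lists 15 passed in MS1262 against wild-type mice, 12 higher and 3 lower, and fry called 9. With an estimated correlation the lysosome list alone held, which ended without wild-type 3 or 4 or MS1262 1 or 4 (adjusted p up to 0.0613; 0.0133 at the lowest). The astrocyte call ended without wild-type 2, 3 or 4 or MS1262 2, 3 or 4 (adjusted p up to 0.157) and the interferon call without wild-type 2 or MS1262 4 (up to 0.183). The synapse call ended without wild-type 2 or 3 or MS1262 1 or 3 (up to 0.131) and the endothelial call without wild-type 3 or 4 or MS1262 3 (up to 0.275). The inhibitory neuron call ended without MS1262 2 (0.0901) and the oxidative phosphorylation call without MS1262 1 (0.0606). Over single omissions the lowest adjusted p of these 6 lists were 0.0155, 0.000467, 0.00601, 0.00202, 0.00891 and 0.000177.

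A further comparison asks whether MS1262 moved expression back toward wild-type levels. The log2 fold changes of vehicle against wild-type and of MS1262 against vehicle were correlated across 17693 genes, which are not independent replicates. Pearson's r was −0.374 and Spearman's rho −0.343, but both comparisons share the vehicle libraries, and simulated unchanged groups gave a mean r of −0.502. The covariance was −0.0999, within the simulated −0.112 to −0.0948 (mean −0.103). With different vehicle animals in each comparison, r over the 6 splits averaged 0.0469 (−0.0304 to 0.140).

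m6A enrichment, the IP over input ratio of a gene, was higher in 5xFAD vehicle than in wild-type mice for 176 genes and lower for 5. For Gfap the IP minus input difference was 1.76 ± 0.21 log2 CPM in vehicle and 0.37 ± 0.36 in wild-type animals, a 2.63-fold rise (SD, n = 4, log2 1.39, SE 0.17, edgeR adjusted p = 0.00210). Trem2 rose 2.59-fold (0.70 ± 0.22 against −0.65 ± 0.30, log2 1.37, SE 0.20, adjusted p = 0.00550). The purinergic receptor gene P2ry6 had the largest rise by the naming rule (log2 1.75, SE 0.38, adjusted p = 0.0367). It was followed by the biliverdin reductase gene Blvrb (1.57), Znrd2 (1.54), the complex I subunit gene Ndufb7 (1.53), the methyltransferase gene Ntmt1 (1.53), the LIM protein gene Crip2 (1.52), Zfp414 (1.495) and the kinetochore gene Cenps (1.48). Lower were Prune2 (log2 −0.93, SE 0.17, adjusted p = 0.0160) and the amino acid transporter gene Slc7a6 (−0.63, adjusted p = 0.0415), among others. Atxn1l (−0.67, adjusted p = 0.0546) and the catenin gene Ctnnd1 (−0.59, adjusted p = 0.0568) did not pass, nor did Cst7 (1.84, adjusted p = 0.121) or the other genes named in advance.

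**Figure D3:**
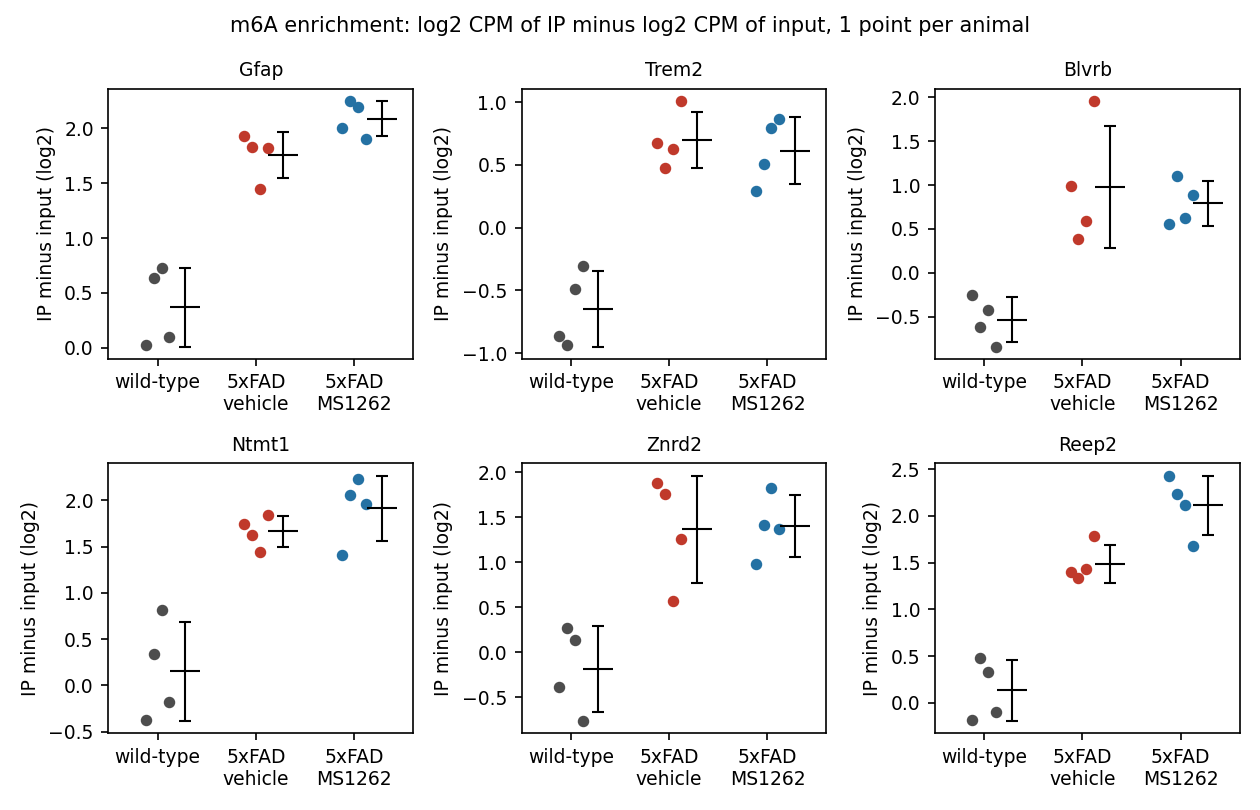
IP minus input difference (log2 CPM) of 6 named genes, 1 point per animal, with the mean and SD of each group. For Gfap the group means are 0.37 in wild-type, 1.76 in vehicle and 2.09 in MS1262 animals.

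The input and IP parts of the m6A change were read in animals other than those that chose the genes. Genes called higher in 1 5xFAD group against 2 wild-type animals were measured in the other group against the other 2. In the 9 of 12 such splits with calls, of 3 to 125 genes, the median IP difference was 0.31 to 0.90 log2 CPM and the median input difference −0.89 to −0.09. Of the 176 higher genes 13 were also called in expression. Their relative effective length had a median of 0.648, against 1.11 for all tested genes. In total 181 of 18300 genes passed the edgeR interaction test, 71 of them at least 2-fold. Without the animal as a block edgeR called 0, and limma on the difference per animal called 0. The IP libraries alone gave 91 genes, of which 4 were shared, and the 16 libraries of both groups 76. DESeq2 called 471, edgeR with no filter on low counts 489 and with a filter of 1 CPM in 4 input libraries 287.

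Single animals also moved the m6A calls of vehicle against wild-type. Leaving out wild-type 1, 2, 3 or 4 gave 39, 113, 114 or 33 genes in place of 181. Leaving out vehicle 1, 2 or 4 gave 41, 112 or 408, and vehicle 3 and 4 together 343. Of the named genes, 0 of 25 m6A calls in all comparisons held in every alternative. 6 of the named genes lost their calls without wild-type 1 and without wild-type 4. P2ry6 lost it in 6 of 8 single omissions (adjusted p up to 0.147), also without wild-type 2 or 3 or vehicle 1 or 3. Blvrb lost it in 5 (0.140), also without wild-type 2 or 3 or vehicle 1, and Znrd2 in 4 (0.124), also without vehicle 1 or 2. Cenps lost it in 7 (0.170), all but that of wild-type 2, and Slc7a6 in 7 (0.179), all but that of vehicle 4. Prune2 lost it in 3 (0.0850), also without wild-type 3. The lowest adjusted p over single omissions were 0.0237, 0.0271, 0.0111, 0.0357, 0.0267 and 0.00224 in this order. Atxn1l (0.0421) and Ctnnd1 (0.0296) passed without vehicle 4, as did Thy1 (0.0380), and Cst7 passed without wild-type 3 (0.0397); the highest were 0.223, 0.180, 0.730 and 0.368.

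In MS1262 against wild-type mice, m6A enrichment was higher for 223 genes and lower for 4. The endoplasmic reticulum shaping gene Reep2 rose most by the naming rule (log2 1.99, SE 0.20, edgeR adjusted p = 0.000206). Gfap rose 3.30-fold (2.09 ± 0.16 against 0.37 ± 0.36, SD, n = 4, log2 1.72, SE 0.17, edgeR adjusted p = 0.000206) and Trem2 2.45-fold (log2 1.29, SE 0.20, adjusted p = 0.00459). Further rises were Ntmt1 (1.77), the transcription regulator gene Id3 (1.76), the peroxisome gene Pex6 (1.74), Nosip (1.59), the collagen chaperone gene Serpinh1 (1.59) and Znrd2 (1.58). The aminopeptidase gene Anpep (log2 −1.74, SE 0.34, adjusted p = 0.0186), Stard13 (−0.75, adjusted p = 0.0273) and Ctnnd1 (−0.62, adjusted p = 0.0333) were lower. Aatf (−0.73, adjusted p = 0.0592), Usp29 (−0.50, adjusted p = 0.0633) and Cst7 (2.08, adjusted p = 0.0554) did not pass. Of the genes higher in either comparison with wild-type 134 were shared, against 2.14 for independent lists. When different wild-type animals served as controls for each group, 0 to 3 were shared (mean 1.33, with 0.00438 for independent lists), and no lower gene was shared.

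Of the 223 genes higher in MS1262 than in wild-type mice 15 were also called in expression. In total 227 of 18300 genes passed the edgeR interaction test, 86 at least 2-fold. Without the animal as a block 1 gene passed, and limma called 51, or 0 with the length trend removed. The IP libraries alone gave 114 genes with 8 shared, and the 16 libraries of both groups 733. With no filter there were 502, and DESeq2 called 497, 424 higher and 73 lower. Without wild-type 1 or 4 the counts were 58 and 65, and without MS1262 2, 3 or 4 they were 84, 67 and 106. Stard13 and Ctnnd1 lost their calls in all 8 single omissions (adjusted p 0.0519 to 0.106 and 0.0622 to 0.129). Serpinh1, Znrd2 and Anpep lost theirs in 5, 5 and 4 of 8 (up to 0.0906, 0.0815 and 0.0783; lowest 0.0288, 0.0237 and 0.0285), each without wild-type 1 or 4 or MS1262 2 or 3, Serpinh1 also without wild-type 3 and Znrd2 also without MS1262 4. Cst7 passed without wild-type 3 (0.0202, highest 0.241).

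Between MS1262 and vehicle no gene passed in m6A enrichment. The ratio of Gfap differed by a log2 value of 0.33 (SE 0.17), of Trem2 by −0.08 (SE 0.18) and of Cst7 by 0.24 (SE 0.22). The m6A enzyme genes Mettl3 (0.13), Mettl14 (−0.06), Fto (0.10) and Alkbh5 (−0.02) and the methyltransferase genes Ehmt1 (−0.13) and Ehmt2 (−0.17) did not pass. The smallest p values, none passing, were those of Pef1 (log2 0.51), Bin3 (0.76), Klhl1 (1.29), Snx11 (1.24) and Myh15 (0.95) on the higher side. On the lower side they were those of Tmem63b (−1.24), Ppm1f (−1.05), Slc25a15 (−0.91), Efcab5 (−0.87) and Pofut2 (−0.68). Of 18300 genes 0 passed the edgeR test, the smallest adjusted p was 0.834, and 434 had an unadjusted p below 0.05. DESeq2 called 3, limma 0, and edgeR with no filter on low counts 42, 18 higher and 24 lower.

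Across 18300 genes, which are not independent, the m6A change of vehicle against wild-type had r = −0.494 and rho = −0.406 with that of MS1262 against vehicle. Simulated unchanged groups gave a mean r of −0.522. The covariance of −0.257 lay beyond the simulated −0.191 to −0.171 (mean −0.179). The 6 splits with different vehicle animals averaged r = 0.00425 (−0.0325 to 0.0318) and a covariance of 0.00386.

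Of the lists tested for m6A enrichment, the mitochondrially encoded genes passed in 2 comparisons. They were lower in vehicle than in wild-type animals (median log2 −0.51, camera adjusted p = 0.00117, 0.880 at estimated correlation). They were higher in MS1262 than in vehicle animals (0.50, adjusted p = 0.000119, 0.978 at estimated correlation). Both calls ended without vehicle 4, whose IP library was the shallowest (adjusted p = 0.0853 and 0.156; 5.26e-07 to 0.880 and 6.03e-09 to 0.978 over all alternatives). In MS1262 against wild-type mice 0 lists passed camera and 1 passed fry, the disease-associated microglia genes (camera adjusted p = 0.108, median 0.10). They passed camera upward without wild-type 4 (0.0336, highest over single omissions 0.347), and in MS1262 against vehicle without vehicle 4 (0.0236, highest 0.953). The ribosomal protein list passed upward in vehicle against wild-type without wild-type 1 or 4 or vehicle 1 or 2 (0.00124 at the lowest, 0.949 at the highest). In MS1262 against vehicle it passed downward without vehicle 1 or 2 or MS1262 1 (4.56e-05 at the lowest, 0.823 at the highest) and upward without vehicle 4 (0.00541), as did oxidative phosphorylation genes (0.0165, highest 0.966). No m6A list held at estimated correlation in any single omission (0.188 at the lowest).

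The authors' peak lists, called for each animal against its own input, were compared last. Peaks per animal numbered 4265.8 ± 612 in wild-type, 5310.5 ± 1399 in vehicle and 5345.8 ± 717 in MS1262 mice (SD, n = 4). A 2-sided exact permutation test gave p = 0.257 for vehicle against wild-type, p = 0.971 for MS1262 against vehicle and p = 0.0857 for MS1262 against wild-type. Adjusted over the 3 comparisons these were 0.386, 0.971 and 0.257, and the smallest p of this exact design is 0.0286. The difference of 35.25 peaks between MS1262 and vehicle turned negative without vehicle 2 (−470.25), vehicle 3 (−250.58), MS1262 3 (−50.8) or MS1262 4 (−215). It grew to 399.75, 462.08, 352.83 and 54.2 without vehicle 1, vehicle 4, MS1262 1 and MS1262 2. That of vehicle against wild-type (1044.8) shrank to 680.25 or 617.92 without vehicle 1 or 4.

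The number of peaks was also set against depth. Across the 12 animals it had r = 0.329 with the IP tags left after duplicate removal (permutation p = 0.295, adjusted over 2 relations 0.295) and rho = 0.406 (permutation p = 0.193). Without wild-type 2 and vehicle 4, the animals farthest from the median IP depth, r was 0.910 over 10 animals. Within wild-type, vehicle and MS1262 animals r was 0.810, 0.0192 and 0.786, each over 4 animals. With the input tags r was 0.409 (permutation p = 0.184, adjusted 0.295) and rho 0.413 (permutation p = 0.185), and r was 0.139 without vehicle 2 and wild-type 3, the farthest in input depth. Vehicle 4 had 6591 peaks from 5.48 M IP tags, 66.1% of them shared with another animal, against 88.4 to 96.6% in the others.

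**Figure D4:**
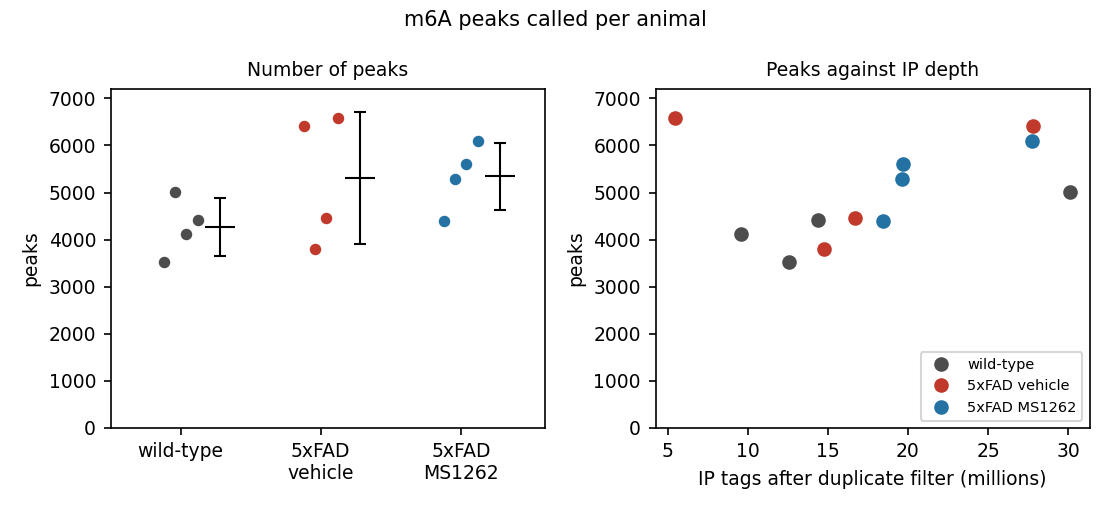
Left, number of m6A peaks per animal by group, 1 point per animal, with the mean and SD; right, the same numbers against the IP tags (M) after the duplicate filter. The groups overlap, from 3534 to 5004 peaks in wild-type, 3794 to 6591 in vehicle and 4393 to 6097 in MS1262 animals.

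Merging the 12 lists gave 13683 peaks, of which 5194 (38.0%) were found in a single animal and 806 in all 12. A peak in Gfap was present in 4 of 4 vehicle and 4 of 4 MS1262 animals and 0 of 4 wild-type animals. It spans GRCm38 chromosome 11, 102895291 to 102895967 (677 bases, mean fold enrichment 6.43 as the authors' caller gave it); whether it lies in an exon was not analysed here. Peaks in the glutamate transporter gene Slc1a1 (chromosome 19, 28835136 to 28835462) and in Arf4 (chromosome 14, 26638176 to 26638633) were found in 4 of 4 vehicle and 0 of 4 wild-type animals. Peaks in the neuronal genes Kalrn (chromosome 16, 34171124 to 34171513), Dclk1 (chromosome 3, 55461947 to 55462180) and Ptprd (chromosome 4, 76128493 to 76129103) were found in 4 of 4 wild-type and 0 of 4 vehicle animals. In MS1262 but not wild-type animals lay peaks in Rab11b (chromosome 17, 33760057 to 33760303) and Ndufb7 (chromosome 8, 83566823 to 83567099). In wild-type but not MS1262 animals lay peaks in Slc1a1 (chromosome 19, 28878923 to 28879242), Dclk1 and Eif4a1 (chromosome 11, 69668085 to 69668648). Peaks in Trap1, Calu and Armc1 were found in 4 of 4 MS1262 and 0 of 4 vehicle animals. Peaks in Aprt and Wasf1 (4 of 4) and Mmd2 (3 of 4) were found in vehicle and in 0 of 4 MS1262 animals.

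Peaks present in at least 3 of 4 animals of 1 group and none of the other numbered 408 for vehicle against wild-type (332 with vehicle, 76 with wild-type). They numbered 169 for MS1262 against vehicle (115 and 54) and 746 for MS1262 against wild-type (576 and 170). With all 4 animals required the counts were 90, 14 and 226, and 1 peak at a time has no test that can pass adjustment with 4 animals per group. With an animal left out, the rule asked for 2 of the 3 left in its group and for none of 3 on the other side, which raised the counts. For vehicle against wild-type they rose to 614, 831 and 674 without wild-type 1, 2 and 3 and to 638, 844, 804 and 944 without vehicle 1 to 4. For MS1262 against vehicle they were 415, 372, 342 and 409 without vehicle 1 to 4 and 411, 345, 338 and 333 without MS1262 1 to 4. For MS1262 against wild-type they were 1334 without wild-type 2 and 1250 without MS1262 1.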

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

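The gene and list split tests were planned and their predictions written before the results were seen; the tests of peak splits and all tests of the 3 weighed patterns were chosen after the results were seen. Among 426 groups of 4 values, 25 held a value far from the other 3 (by Dixon's test of the gap over the range), and chance alone gives about 5% of groups.

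The first pattern is set by vehicle animal 3, whose input had a choroid plexus list mean of 6.94 log2 CPM, against 2.48 for the next vehicle animal, and a complement and antigen presentation mean of 1.99, against 2.89. Choroid plexus tissue in this sample may account for the lower choroid plexus markers of MS1262 against vehicle, since without this animal the median was −0.113 in place of −2.77. A change in all vehicle animals is argued against, as only 1 of 4 vehicle animals lay above all MS1262 animals. A swap with a wild-type animal is argued against by Thy1 at 273 CPM and Cst7 at 7.48 CPM, against at most 104 and 0.491 in wild-type animals. How much the other lists of this animal reflect its tissue makeup was not tested, and a swap with another 5xFAD or an outside animal stays open.

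The second pattern is a set of 13 genes, chosen after their values were seen, that were at least 4-fold lower in both 5xFAD groups than in wild-type animals, among them Tmem242, Lsm12, Gt(ROSA)26Sor, Etv4, Fbxo5, Rps3a2, Rps3a3 and Gm10259, which had 2539 counts over the wild-type input libraries and 0 over the 8 5xFAD ones. Their medians were −3.88 and −3.91 for vehicle and MS1262 against wild-type, with genes at 0 placed at their bound as well. An IP median of −3.26 argues against a loss in input libraries alone. A single linked interval is argued against by 1 gene pair within 2 Mb (1589 of 10000 random sets reached it). Reads shared with related sequences may contribute, because 53.8% of the set were pseudogenes against 3.90% of tested genes (Fisher's exact p = 1.85e-07). Several linked segments, a sequence difference between strains, the genotype and the dosing of 5xFAD mice alone stay open and untested.

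The third pattern is the higher m6A enrichment of shorter transcripts in both 5xFAD groups. Gene length stays open. Removing each animal's length trend left 92.7% of the median change of called genes in the comparison that lost more (0.93 before, 0.86 after). The genes were chosen in the libraries measured, so this cannot settle it, and limma then called 0 in place of 51. Input libraries as the only source are argued against where genes were chosen in 1 5xFAD group and measured in the other against different wild-type animals, with 27.6 to 90.7% of the change in IP libraries over the splits with calls, and the shallow IP library of vehicle 4 by the 408 genes called without it. RNA integrity, which could act on short and long transcripts unequally, genotype and dosing stay open and were not tested. The calls depended on the model.

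Splits of the 8 animals of each comparison into other groups of 4 bear on chance. For vehicle against wild-type the real grouping gave 278 genes in expression and no other of the 35 splits more than 1. In m6A enrichment it gave 181 against 0 at most. For MS1262 against wild-type, 230 and 227 genes stood against at most 1 and 2. These argue against chance, with 1 split as large, the real one, the smallest unadjusted share 35 splits allow. For MS1262 against vehicle the real groups gave 0 genes in both, as all 35 splits gave as many or more, up to 11 and 1. Chance cannot be excluded for the number of lists, with 16 in vehicle against wild-type (3 splits as large, highest other 16), 10 in MS1262 against vehicle (13 splits, highest other 15) and 15 in MS1262 against wild-type (4 splits, highest other 18). For m6A lists the real counts of 1, 1 and 0 were reached by all 35 splits, with highest others of 6, 4 and 4. Peaks in at least 3 of 4 animals of a group and none of the other numbered 408 (2 splits as large, highest other 620), 169 (15 splits, highest other 378) and 746 (1 split, highest other 609). Chance is thus argued against only for MS1262 against wild-type.

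Other single values stood apart, and by sex-linked genes both libraries of 1 animal did not match their group's labels. Mitochondrial genes took 7.17% of the IP of wild-type 1 (next 5.35%) and 4.22% of the IP of vehicle 4 (next 6.18%), whose ribosomal protein share was 1.79% (next 0.95%). List means apart in log2 CPM were autophagy in wild-type 3 (5.16, next 5.32), proliferation in wild-type 3 (0.988, next 1.19) and MS1262 1 (1.35, next 1.74), meninges and fibroblast in vehicle 2 (1.75, next 3.11), unfolded protein and heat shock in vehicle 2 (5.79, next 5.84) and m6A writers in wild-type 1 (4.29, next 4.15).

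Input CPM values apart were Bcl2a1b in wild-type 1 (3.44), Mettl14 in wild-type 1 (15.7), Tmem242 in wild-type 1 (152), F13a1 in MS1262 1 (2.44) and Mir124-2hg in MS1262 1 (34.6). Differences of IP minus input in log2 CPM apart were Aatf in wild-type 2 (−0.0675), Klhl1 and Pcdhga11 in wild-type 3 (−0.0336 and 4.10), Fto and Pcdhga3 in MS1262 1 (0.47 and 1.76), Pcdhgc3 and Ppm1f in vehicle 1 (6.85 and 1.42), and mt-Rnr1 and Siva1 in vehicle 4 (−4.07 and −0.19).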

How the results depend on the processing

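Removal of the length trend and omission of vehicle 3 and 4 together were chosen after the data had been seen; every other alternative was planned. Of 5386 recomputed values of named genes and lists, 4951 kept direction and side of the threshold, 337 dropped below it, 86 rose above it and 12 reversed. Of 36 named expression calls 30 held in every alternative, of 25 m6A calls 0, and of 27 IP against input calls 25. The cause was not tested where none is given. With DESeq2 the expression counts of vehicle against wild-type, MS1262 against vehicle and MS1262 against wild-type were 611, 11 and 633 and the m6A counts 471, 3 and 497; with no low-count filter the m6A counts were 489, 42 and 502. Fewer libraries gave 118 expression genes (8 libraries) and 76 and 733 m6A genes (16 libraries) for vehicle and MS1262 against wild-type. limma on log2(TPM + 1) and log2(TPM + 0.1) gave 124 and 145 for MS1262 against wild-type. A filter of 1 CPM in 4 input libraries gave 287 m6A genes for vehicle against wild-type, IP libraries alone 91 and 114, limma on the difference 0 and 51, and with the length trend removed 0 and 0. Without vehicle 3 and 4, 343 m6A genes (vehicle against wild-type) and 2 expression genes (MS1262 against vehicle) passed. The replicate number as a block gave 134 and 168 expression genes against wild-type for vehicle and MS1262; the numbers share no design, correlations of same-numbered animals ran from −0.0938 to 0.126, and most libraries did not correlate best with their own number. Without the animal block that pairs input and IP, m6A counts were 0 and 1.

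Lists with an estimated correlation numbered 5, 0 and 1 in expression and 0 in each m6A comparison, with fry 0 for MS1262 against vehicle, 9 for MS1262 against wild-type, and 0, 0 and 1 for m6A. Single omissions gave 108 to 297, 0 to 2 and 105 to 174 expression genes, 33 to 408, 0 and 58 to 180 m6A genes, 9641 to 10792 for IP against input, 14 to 17, 10 to 14 and 12 to 16 lists and 0 to 2, 1 to 3 and 0 to 1 m6A lists. They gave differences in peak number of 617.92 to 1550.2, −470.25 to 462.08 and 829.58 to 1397.6 and peaks by presence of 559 to 944, 333 to 415 and 907 to 1334. Peaks of at least 5-fold enrichment turned the differences of MS1262 against vehicle and wild-type to −46.25 and −0.25, and peaks in all 4 animals against none numbered 90, 14 and 226. Correlations of opposite change were −0.0575 and −0.916 in called genes, chosen from the same vehicle libraries and so no evidence, −0.530 for m6A under a stricter filter, −0.539 to −0.499 and −0.611 to −0.562 in single omissions, and in vehicle splits 0.140, −0.0304, −0.00886, 0.0854, 0.0284 and 0.0671 for expression and 0.00223, 0.01002, 0.00887, −0.0325, 0.0318 and 0.00514 for m6A.

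Reversed items were Thy1, higher in IP libraries alone (log2 1.99 and 2.15 against wild-type), and 5 lists, by the direction of their test. Choroid plexus of vehicle against wild-type turned lower without vehicle 3 (adjusted p = 0.0337; 0.00875 to 0.395 over single omissions) or 3 and 4 (0.0425). For MS1262 against vehicle without vehicle 3 or 3 and 4, disease-associated microglia (0.00428, 0.000136; 0.00428 to 0.788), complement (0.0199, 0.0222; 0.0199 to 0.824) and choroid plexus (0.966, 0.693; 3.66e-05 to 0.966) turned, although the choroid plexus median stayed negative without vehicle 3 (−0.113) and that of complement was negative throughout (−0.0474, −0.255, −0.217). In m6A of MS1262 against vehicle without vehicle 4, oxidative phosphorylation (0.0165 to 0.966) and ribosomal proteins (0.00541; 4.56e-05 to 0.823) reversed.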

Other observations

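The tests named here were planned. Among lists not described above, hippocampal neuron markers did not pass in vehicle against wild-type mice, with dentate gyrus genes at a median log2 of 0.08 (camera adjusted p = 0.608), CA1 and CA3 pyramidal genes at −0.08 (0.448), excitatory neuron genes at −0.06 (0.301) and synaptic genes at −0.06 with a mean of 0.01 (0.725, signs differ). Oligodendrocyte genes (−0.06, 0.338), oligodendrocyte precursor genes (0.15, 0.330), endothelial and mural markers (0.21, 0.301) and thalamus and striatum markers (0.61, 0.0802) did not pass either. Without vehicle 3 the oligodendrocyte list passed on the lower side (adjusted p = 0.00499 against 0.924 at the highest over single omissions), without wild-type 4 the endothelial list passed (0.0234, highest 0.825), and the thalamus list passed without wild-type 2, vehicle 2 or vehicle 4 (0.0154 at the lowest, 0.825 at the highest); none of these held with an estimated correlation (0.310 at the lowest).

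Genes of the drug's pathway and of RNA methylation did not pass camera in vehicle against wild-type mice, with members going both ways. H3K9 methylation genes had a median of 0.05 (adjusted p = 0.866), with m6A writers at −0.08 (0.433), m6A erasers and readers at −0.02 with a mean of 0.07 (0.521, signs differ) and germline genes, which H3K9 methylation keeps silent, at −0.05 with a mean of −0.38 over 6 tested members (0.338). Autophagy genes (0.02, 0.866, test downward), unfolded protein and heat shock genes (0.725) and oxidative phosphorylation genes (0.02, 0.856, test downward) did not pass. Between MS1262 and vehicle the germline list had a median of 0.08 (0.452), m6A erasers and readers 0.06 (0.128), autophagy genes −0.00 (0.577), immediate early genes 0.06 with a mean of −0.02 (0.177, signs differ), dentate gyrus genes 0.19 (0.144), CA1 and CA3 genes 0.15 (0.107), oligodendrocyte genes −0.11 (0.354), oligodendrocyte precursors 0.09 (0.627), inhibitory neuron genes −0.03 (0.641), amyloid processing genes 0.06 (0.204), cholesterol synthesis genes 0.02 (0.641), proliferation genes −0.06 (0.501) and unfolded protein and heat shock genes 0.01 (0.633). Immediate early genes passed without vehicle 4 (0.00389, highest 0.769). The dentate gyrus list passed upward without vehicle 3 (0.0208) and without MS1262 4 (0.00326, highest over single omissions 0.596), and the CA1 and CA3 list without MS1262 1 (0.00787, highest 0.363); none of these held with an estimated correlation (0.398 at the lowest).

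The mixed form of fry, for change in either direction, passed 14, 0 and 17 lists in expression (vehicle against wild-type, MS1262 against vehicle, MS1262 against wild-type), of which 2, 0 and 4 did not pass camera. The 2 were synaptic genes (adjusted p = 0.0218) and H3K9 methylation genes (0.0284). In m6A enrichment it passed 10, 0 and 12 lists, none of which passed camera.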
